A study of Homo sapiens with 9 samples.

How the data were processed

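Total RNA from 3 breast cell lines was profiled on 9 single-colour miRNA arrays labelled with Cy3 and run as a service, per the labels' protocols. Each of the 9 groups holds 1 array, so no comparison of a pair of groups has a replicate check and no p-value is given for one. Per the labels, SUM52 and SUM225 cells were left untreated or given 4μ8C for 2 days, SUM52 cells carried GFP, K599A or K907A, and MCF10A cells carried GFP or IRE1. Array batches are not given in the sources used here.

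The values are spot intensities on a linear scale, which the authors deposited before and after background subtraction. The values show that 1 background level per block of the array was subtracted and that spots at or below 0 were set to 0.01. Of 74385 spots compared between the deposited processed and background-subtracted intensities, 0 differed. Each of 2555 human miRNA probes had 3 spots, and each array had 1771 empty spots. The authors also deposited a table with 1 intensity per probe and array in whole numbers, whose normalization is not given in the sources used here. On the log2 scale its human miRNA values correlated with the spot means of their own array at r from 0.946 to 0.998 across miRNAs, which are not independent replicates. Its column medians were 6 and 25 for untreated SUM52 and SUM225, 34 and 32 for these lines with 4μ8C, 15, 14 and 14 for SUM52 with GFP, K599A and K907A, and 16 and 18 for MCF10A with GFP and IRE1. Its control probes did not follow the spot tables by name (r from -0.0959 to 0.200), so only its human miRNAs were used, as an alternative. How that table was centred stays unknown.

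The background-subtracted spots of each probe were averaged, quantile-normalized over the 9 arrays with limma 3.58.1 in R 4.3.3, raised to a floor of 32 and taken to log2. Files were read with Python 3.11.15 and pandas 2.3.3. A miRNA counted as detected on an array when its mean lay above the higher of 3 times the block background SD and the 95th percentile of the empty spots. This definition was set after the files had been opened and before any comparison was made. The limit ran from 41.4 on the K599A array to 409 on the MCF10A GFP array, before normalization. The 49 probes that are not human miRNAs, 6 of them for human 5S RNA among them, entered no normalization and no test. The error beside a log2 ratio is the SD over the 3 spots, combined over both arrays. It covers spotting and scanning only, and the number of arrays limits the precision.

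A 2-fold count covers miRNAs detected on at least 1 of the 2 arrays. Where the dimmer array did not detect a miRNA, its fold is given as a lower bound, with the dim side at the higher of its own level and the lowest normalized level of a detected miRNA on that array. The named miRNAs of each comparison follow a rule written before the data were examined. It takes those at or beyond 2-fold with a normalized signal of at least 500 on the brighter array, up to 12 in each direction, the 10 smallest p-values of the common effect where fewer than 10 pass, and the members of each list with the highest signal. The ranking was restricted to miRNAs detected on both arrays after the data were examined, since values at the floor have no order. Other miRNAs named were chosen after their values were seen.

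The common effect of blocked IRE1 was fitted with limma (lmFit and eBayes) to 7 arrays, 4 with IRE1 blocked and their 3 controls. The fit had 3 blocks and 3 residual degrees of freedom. The blocks were the inhibitor arrays of SUM52, those of SUM225, and the mutant and GFP arrays of SUM52. It covered 555 miRNAs detected on at least 2 of these arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 blocked arrays hold different conditions, and nothing says that samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. A second limma fit tested the difference between the inhibitor and the mutants, with 2 residual degrees of freedom. In data simulated for the common effect over 555 miRNAs, 100 were changed 2-fold, 100 were changed 4-fold and 355 were unchanged. Of these, 44, 90 and 3 were called. Such rates hold only for that share of changed miRNAs, since the Benjamini-Hochberg threshold is stricter where fewer change. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, which was not in the plan. In single comparisons the median of a list was placed among 10000 random lists of the same size matched on mean signal, as a description of those arrays.

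The 18 lists, fixed before the data were examined, cover IRE1 cleavage substrates from the literature, the unfolded protein response, the let-7, miR-200 and miR-205, miR-17-92, miR-15/16, miR-29, miR-30, miR-34 and p53, miR-23/27/24 groups, the cluster of miR-182, miR-183 and miR-96, breast tumour suppressor and oncogenic miRNAs, hypoxia, and markers of blood, immune and endothelial cells, of fibroblasts and muscle, of basal mammary cells, and of liver and neural cells. miR-374a-5p and miR-3607-3p were placed in the tumour suppressor list from memory of the study itself. Some lists share members, and results of such lists are not independent. For example, miR-200a-3p, miR-200b-3p and miR-200c-3p are also among the IRE1 cleavage substrates.

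Alternatives changed the normalization, the floor, the detection filter, the summary of spots, the background correction, the block, the settings of eBayes and the arrays used, or replaced the spot data with the authors' table. Names are those of the array design. No genome build is named for it, so no coordinates are given. Probes for family members with nearly the same sequence, such as those of let-7, miR-320 or miR-17 and miR-20, can share signal, and values of single members are uncertain for that reason. mRNA was not measured on these arrays, so the blocking or raising of IRE1 itself has no check here.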

Results

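The arrays addressed which miRNAs differ when IRE1, an endoplasmic reticulum stress sensor with kinase and RNase activity, is blocked or raised in breast cells. SUM52 and SUM225, both breast cancer lines, were compared with and without 4μ8C, an inhibitor of the IRE1 RNase. SUM52 cells carrying the dominant-negative forms K599A, changed in the kinase domain, or K907A, changed in the RNase domain, were compared with cells carrying GFP. MCF10A, a non-tumorigenic mammary epithelial line, was compared with IRE1 and with GFP. Each group holds 1 array and there are no replicates. Between 343 (untreated SUM52) and 611 (SUM52 with 4μ8C) of 2555 human miRNAs were detected. The subtracted background level ran from 77.2 on the K599A array to 559 on the untreated SUM52 array. In 17 usable pairs of control probes, whose naming is not explained in the sources used here, the probe named M or MM read a median of 36.6% of its partner named P or PM with 4μ8C in SUM52 and 3.95% without, and 26.7% with 4μ8C in SUM225 and 1.21% without. The medians were 0.546%, 0.600% and 0.617% for SUM52 with GFP, K599A and K907A, and 28.4% and 21.0% for MCF10A with GFP and IRE1.

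**Figure D1:**
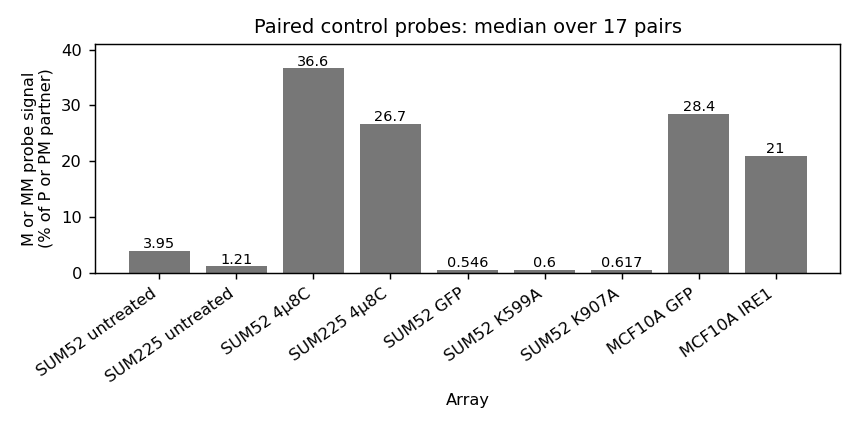
Median signal of the control probe named M or MM in percent of its partner named P or PM (vertical axis) over 17 pairs, for each of the 9 arrays (horizontal axis). The 4μ8C arrays, at 36.6% and 26.7%, and the MCF10A arrays, at 28.4% and 21.0%, lie above the other 5 arrays, the highest of which is at 3.95%.

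In SUM52 cells given 4μ8C, 5 members of the miR-320 family were among the 12 miRNAs with the lowest ratios. miR-320a was 3.58-fold lower (log2 ratio -1.84 ± 0.32, SD over spots), miR-320c 3.51-fold, miR-320e 3.34-fold, miR-320b 3.31-fold and miR-320d 3.08-fold lower, and the family median stayed below 0 under each scaling tried (from -1.74 to -0.44). miR-7843-5p (5.69-fold), miR-98-5p of the let-7 family (5.48-fold), miR-181c-5p (4.38-fold), miR-381-5p (4.25-fold), miR-195-5p of the miR-15/16 family (4.21-fold), miR-1908-5p (4.16-fold) and miR-374a-5p (3.93-fold, log2 ratio 1.97 ± 0.32) had the highest ratios. Among the lower ones were also miR-4514 (3.92-fold), miR-3609 (3.78-fold), miR-564 (3.73-fold), miR-92b-3p (2.90-fold), miR-378e (2.82-fold) and miR-7-5p (2.74-fold), and miR-361-5p had a log2 ratio of -1.76 with a spot SD of 1.77. miR-4764-3p, not detected without 4μ8C, was at least 9.78-fold higher, and miR-498, not detected with it, at least 6.75-fold lower. At or beyond 2-fold were 180 higher and 59 lower of 621 miRNAs, but 23 higher and 43 lower of the 333 detected on both arrays. The share of higher ones, 75.3%, ran from 52.6% to 95.1% over the scalings. The untreated array had a detection limit of 322, against 108 with 4μ8C, and 46.1% of its miRNA spots were set to 0.01, against 18.3%.

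In SUM225 cells given 4μ8C, the same 5 miR-320 miRNAs were among the 12 with the lowest ratios, from miR-320e at 4.54-fold lower to miR-320c at 5.70-fold lower (log2 ratio -2.51 ± 0.17). Their median stayed below 0 under each scaling tried (from -2.33 to -1.04). miR-4267 was 6.78-fold higher, miR-6753-5p 5.79-fold, miR-374a-5p 5.57-fold (log2 ratio 2.48 ± 0.36), miR-1260a 5.18-fold, miR-422a 4.53-fold and miR-29b-3p, which targets collagen mRNAs, 3.34-fold higher (log2 ratio 1.74 ± 0.24). miR-4521 was 4.86-fold lower, miR-568 3.73-fold, miR-4298 3.61-fold, miR-7847-3p 3.28-fold, miR-18a-5p of the miR-17-92 cluster 3.23-fold and miR-361-5p 3.01-fold lower. Another 25 miRNAs were bright with 4μ8C and not detected without it, among them miR-4317 (at least 31.8-fold higher), miR-6820-5p (at least 17.8-fold), miR-4764-3p (at least 15.2-fold) and miR-3607-3p (at least 3.14-fold). miR-34 and p53-responsive miRNAs had a median log2 ratio of -1.22 over 4 members, at percentile 1.41 of random lists, with miR-34a-5p at -1.35; without normalization this median turned to 0.097 with that of all miRNAs at 1.26, and relative to all miRNAs it ran from -1.22 to -1.16 over the scalings. In SUM52 with 4μ8C the same list had a median of -0.0749 over 5 members, at percentile 51.2. Of 508 miRNAs 123 were higher and 110 lower at or beyond 2-fold, and of the 341 detected on both arrays 35 were higher and 77 lower. The share of higher ones, 52.8%, ran from 49.4% to 98.0% over the scalings, the latter without normalization.

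The log2 ratios of both lines with 4μ8C correlated at r = 0.616 (Spearman's rho 0.639) across the 272 miRNAs detected on all 4 arrays; miRNAs are not independent replicates. Of these, 6 were at or beyond 2-fold higher in both lines and 16 lower in both, where independent lists would share 2.00 and 5.07, and 0 lay beyond 2-fold in opposite directions. The 16 include miR-320a to miR-320e, whose probes can share signal. The M or MM control probes of the same arrays read 36.6% and 26.7% of their partners with 4μ8C in SUM52 and SUM225, against 3.95% and 1.21% without it.

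**Figure D2:**
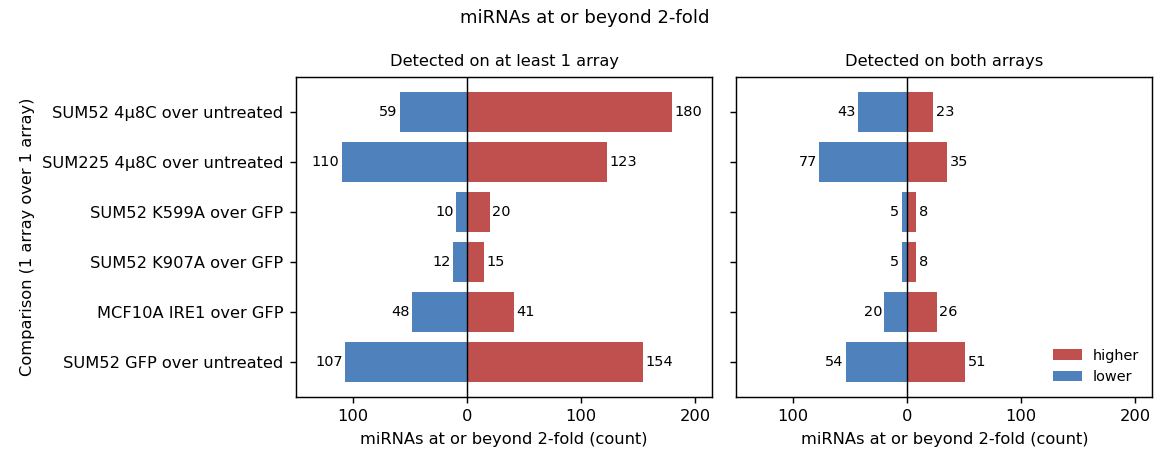
Number of miRNAs at or beyond 2-fold (horizontal axis, higher in the first-named group to the right and lower to the left) in 6 comparisons of 1 array with 1 array (vertical axis). The left panel counts miRNAs detected on at least 1 array and the right panel those detected on both, where SUM52 with 4μ8C goes from 180 higher and 59 lower to 23 higher and 43 lower.

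With K599A in SUM52 cells, miR-4267 was 9.70-fold higher than with GFP, miR-3613-3p 3.58-fold, miR-374a-5p 3.38-fold (log2 ratio 1.76 ± 0.19), miR-422a 2.84-fold, miR-5096 2.61-fold, miR-4668-5p 2.49-fold and miR-4764-3p 2.48-fold higher. With K907A, miR-3613-3p was 7.80-fold higher, miR-4668-5p 6.19-fold, miR-374a-5p 3.91-fold (log2 ratio 1.97 ± 0.38), miR-4764-3p 3.52-fold, miR-4674 2.86-fold and miR-4325 2.38-fold higher, with miR-4267 at 2.04-fold and miR-422a at 2.01-fold. Of these higher miRNAs, miR-4267, miR-3613-3p, miR-4668-5p and miR-5096 were lower with GFP than in untreated SUM52. Whether low readings on the GFP array raised their mutant ratios was not tested. For GFP over untreated, miR-374a-5p and miR-4764-3p had log2 ratios of 0.37 and 2.54. let-7b-5p, of a family known to restrain RAS and HMGA2, had the lowest ratio among bright miRNAs detected on both arrays with either mutant, at 2.81-fold lower with K599A (log2 ratio -1.49 ± 0.12) and 2.60-fold lower with K907A (log2 ratio -1.38 ± 0.04). miR-25-5p, miR-378f and miR-3180 were also at or beyond 2-fold lower with both, miR-196a-5p with K599A and miR-652-3p with K907A. The miR-320 family had a median of -0.61 with K599A and -0.46 with K907A, below 0 under each scaling tried (down to -2.13 and -1.71). miR-485-5p, not detected with GFP, was at least 5.27-fold higher with K599A with a spot SD of 2.90. With K599A 20 of 446 miRNAs were higher and 10 lower at or beyond 2-fold, and with K907A 15 of 438 were higher and 12 lower. The shares of higher ones, 66.7% and 55.6%, were 1.39% and 2.88% without normalization, which put the median of all ratios at -1.16 and -0.94.

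Both mutants were set against the same GFP array. Their log2 ratios correlated at r = 0.836 (Spearman's rho 0.811) across 377 miRNAs, against 0.499 in simulated unchanged groups sharing a control, and their covariance was 0.177 against 0.0350 simulated. Of these miRNAs 7 were higher and 4 lower with both at or beyond 2-fold, where independent lists would share 0.170 and 0.0663. The simulated errors were sized on the differences between the mutants, in which the GFP array cancels. Part of the excess may come from the shared control, which is a single array and could not be split. Ratios with 4μ8C correlated with those of K599A and K907A at r = 0.223 and 0.235 in SUM52 and at r = 0.353 and 0.324 in SUM225.

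**Figure D3:**
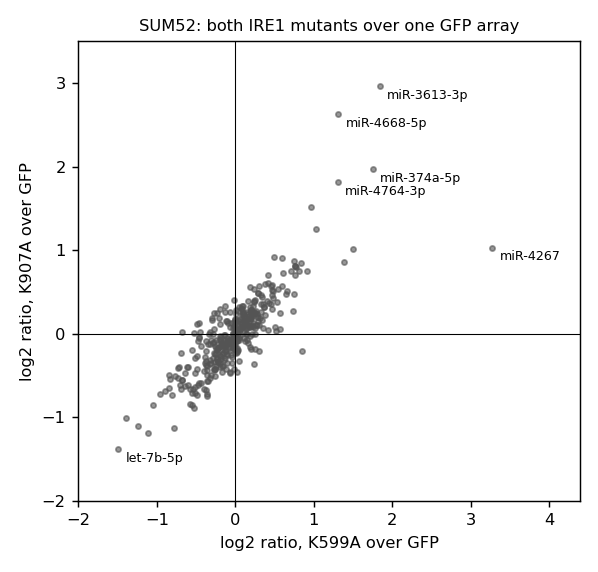
Log2 ratio over the shared GFP array with K599A (horizontal axis) and K907A (vertical axis) in SUM52 cells, where each point is 1 of 377 miRNAs detected on all 3 arrays. miR-374a-5p lies at 1.76 and 1.97, miR-4267 at 3.28 and 1.03, and let-7b-5p at -1.49 and -1.38.

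Across the 4 blocked arrays miR-374a-5p had the smallest p-value, with a common log2 effect of 2.08 (SE 0.24, limma adjusted p = 0.102), higher on 4 of 4 arrays and detected on all 7. miR-3607-3p followed with 1.61 (SE 0.22, limma adjusted p = 0.117), also higher on 4 of 4. It was not detected on any of the 3 control arrays, so its difference is known only as a bound of at least 1.45-fold and 3.14-fold with 4μ8C in SUM52 and SUM225 and at least 1.95-fold and 1.81-fold with K599A and K907A. let-7a-3p (2.24), miR-4318 (1.50), let-7f-2-3p (2.05), miR-4764-3p (3.34) and miR-135b-5p (1.66) were higher on 4 of 4 with limma adjusted p between 0.166 and 0.219, and each was detected on at most 5 of the 7 arrays. let-7i-5p (-1.11), miR-652-3p (-1.09) and miR-320e (-1.51, SE 0.32) were lower on 4 of 4, each with limma adjusted p = 0.219, and were detected on 4, 6 and 7 of the 7 arrays. Ratios between arrays that did not detect a miRNA enter these counts and effects. With limma, 0 of 555 miRNAs passed the threshold, while 48 higher and 35 lower had an unadjusted p under 0.05, against 27.8 by chance. In 8 alternatives between 1 and 3 passed, over the miRNAs detected on all 7 arrays 9 passed, and without the SUM52 GFP array, which leaves the mutants with no control, 45 passed. For the difference between the inhibitor and the mutants limma gave 0 past the threshold, with 99 at an unadjusted p under 0.05 and a smallest adjusted p of 0.142, and 207 and 37 past it without normalization and without the detection filter. On all 4 blocked arrays 75 miRNAs were higher and 87 lower, and 7 were higher and 0 lower at or beyond 2-fold on each. Counts expected without a common effect were not computed, so these counts are no evidence of one. Among miRNAs detected on all arrays compared, signs matched in 77.2% between the lines with 4μ8C. They matched in 82.2% between the mutants, which share a control, and in 55.1% to 58.5% between inhibitor and mutants.

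**Figure D4:**
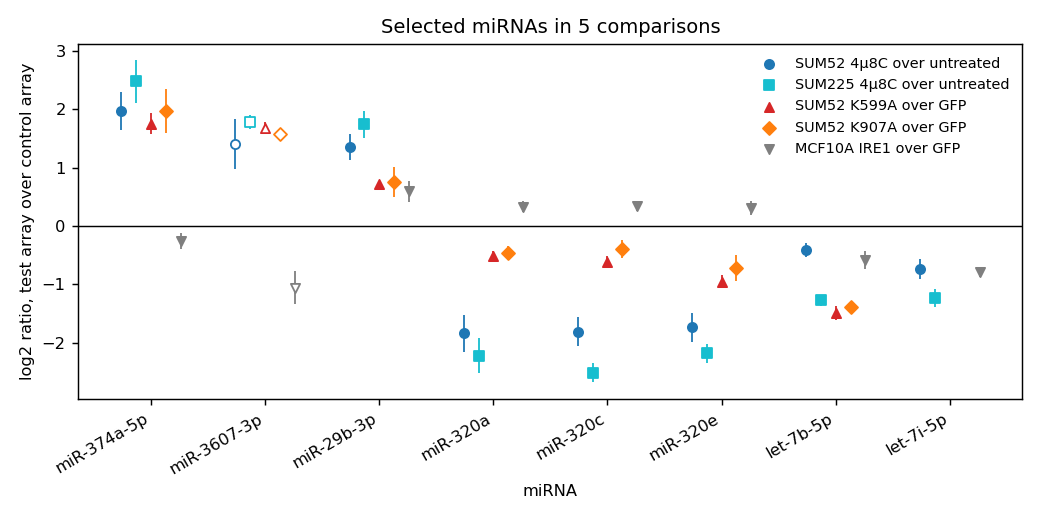
Log2 ratio of the test over the control array (vertical axis) for 8 miRNAs (horizontal axis) in 5 comparisons; bars give the SD over spots, open symbols a miRNA not detected on 1 of the 2 arrays, and let-7i-5p has no value with the mutants, where neither array detected it. miR-374a-5p lies from 1.76 to 2.48 in the 4 comparisons that block IRE1 and at -0.26 with IRE1 in MCF10A.

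The let-7 family passed the list test downward, with a median common effect of -0.55 and 1 of 9 members above 0 (camera adjusted p = 0.00514; adjusted p = 0.711 with an estimated correlation, under which no list passed). Its median was -0.41 and -0.59 with 4μ8C in SUM52 and SUM225, and turned to 0.69 in SUM52 when scaled to all probes and to 0.19 and 0.13 without normalization, where the median of all miRNAs was 1.01, 0.51 and 1.26. Relative to all miRNAs it lay below 0 under each scaling tried, from -0.78 to -0.32 in SUM52 and from -1.13 to -0.56 in SUM225. With K599A and K907A it was -0.68 and -0.56, and below 0 under each scaling tried. It was also below 0 where IRE1 was not blocked, at -0.69 with IRE1 over GFP in MCF10A and at -0.48 with GFP over untreated in SUM52. All 9 members were below 0 in each of these, so a lower let-7 median was not particular to the blocked arrays. Adjusted over the list alone 2 members passed, let-7i-5p (-1.11) and let-7b-5p (-1.08), and 0 over all miRNAs tested. let-7b-5p was lower on 4 of 4 arrays and detected on all 7. Of these 7 arrays let-7i-5p was detected only on the 4 of the inhibitor experiment, so its effect rests in part on mutant ratios between levels below the detection limit. let-7d-5p was at -0.69, let-7a-5p at -0.60, and miR-98-5p, which was detected with neither mutant nor GFP, was the member above 0. The list test gave an adjusted p of 0.234 on the 4μ8C arrays alone, 0.252 without normalization and 0.138 without the SUM52 GFP array. Basal mammary cell markers had a median of -0.67 with 1 of 7 above 0 (camera adjusted p = 0.0523), and passed in 8 of 23 alternatives (camera adjusted p from 0.00398 to 0.591), as the only list without the SUM52 GFP array. With 4μ8C their median was -0.69 in SUM52 and -1.03 in SUM225, at percentiles 2.87 and 4.43 of random lists, with miR-221-3p at -1.04 and -1.31 and miR-22-3p at -1.04 and -1.25, the latter with a spot SD of 3.44; the median turned to 0.34 in SUM52 when scaled to all probes and to 0.16 in SUM225 without normalization, but relative to all miRNAs was -0.67 and -1.10 there, with 6 and 7 of 7 members below them. It was -0.11 and -0.20 with K599A and K907A. In the tumour suppressor list 3 of 20 members passed when adjusted over the list alone, miR-374a-5p, miR-3607-3p and miR-29b-3p (1.22), all higher on 4 of 4 arrays, and 0 over all miRNAs tested; the former pair was placed there from memory of the study, so this count is not independent evidence. That list had a median of -0.11 and a mean of 0.15, and its test pointed down (camera adjusted p = 0.717). In the miR-29 family miR-29b-3p was the 1 of 3 members to pass over its list alone (median 0.37, camera adjusted p = 0.309). miR-210-3p, which hypoxia induces and which is the only member of its list, did not pass over all miRNAs tested (-0.79, limma adjusted p = 0.321, unadjusted p = 0.0261), was lower on 4 of 4 and was not detected with either mutant.

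The other lists did not pass with camera. With fry, which asks whether members move one way and compares them with no other miRNAs, the miR-200 and miR-205 list passed downward (fry adjusted p = 0.0499) and let-7 did not (fry adjusted p = 0.0775). IRE1 cleavage substrates, which a loss of cleavage would raise, had a median of -0.17 with 2 of 8 above 0 (camera adjusted p = 0.309). With 4μ8C in SUM52 and SUM225, miR-125b-5p was at -0.48 and -0.93 and miR-34a-5p at -0.69 and -1.35. miR-96-5p was higher, at 1.13 and 1.10. Unfolded protein response miRNAs had a median of -0.20 over 6 members (camera adjusted p = 0.362). The miR-200 and miR-205 list, whose miR-200 members repress ZEB factors, had a median of -0.19 with 1 of 6 above 0 (camera adjusted p = 0.309). The miR-17-92 group had a median of -0.22 with 3 of 13 above 0 (camera adjusted p = 0.292). Medians were 0.10 for the miR-15/16 family, 0.14 for the miR-30 family, -0.34 for miR-34 and p53-responsive miRNAs, -0.22 for the miR-23/27/24 clusters, -0.43 for the cluster of miR-182, miR-183 and miR-96 and 0.0049 for oncogenic miRNAs, with camera adjusted p between 0.348 and 0.987. Fibroblast and muscle markers had a median of 0.87 with 2 of 3 above 0 (camera adjusted p = 0.348). Of these, miR-145-5p and miR-206, a skeletal muscle miRNA, were detected with 4μ8C in both lines and not without it, at least 1.28-fold and 1.05-fold higher in SUM225 and with no bound above 1 in SUM52. The blood, immune and endothelial list had a median of 0.88 with 1 of 2 members above 0. In it miR-451a, abundant in red cells, was likewise detected only on the 4μ8C array of each pair, at least 1.70-fold higher in SUM225 and with no bound above 1 in SUM52. The liver and neural list had a median of 0.03 over 2 members. On the same 4μ8C arrays the M or MM control probes read 36.6% and 26.7% of their partners.

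In MCF10A cells with IRE1, miR-5096 was 12.4-fold higher than with GFP (log2 ratio 3.63 ± 0.13), miR-4701-5p 6.54-fold, miR-4762-5p 6.36-fold, miR-3126-5p 6.27-fold, miR-548q 5.89-fold, miR-4668-5p 5.51-fold and miR-4734 5.12-fold higher, and miR-3613-3p and miR-4267 were 3.94-fold and 3.24-fold higher. miR-6865-5p was 9.52-fold lower, miR-6820-5p 7.38-fold, miR-3182 6.53-fold, miR-3197 5.97-fold, miR-10a-5p 4.77-fold (log2 ratio -2.25 ± 0.31), miR-4485 4.15-fold and miR-4764-3p 3.81-fold lower. miR-4319, not detected with IRE1, was at least 22.4-fold lower. miR-374a-5p was at -0.26, and miR-3607-3p, not detected with IRE1, was at least 1.10-fold lower. All 9 let-7 members had ratios below 0, with a median of -0.69 at percentile 0.015 of random lists that ran from -1.20 to -0.04 over the scalings. Of 496 miRNAs 41 were higher and 48 lower at or beyond 2-fold. The share of higher ones, 46.1%, ran from 3.23% without normalization to 48.4%. The ratios correlated with those of the 4 blocking comparisons at r from -0.0951 to 0.185 across miRNAs.

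The control arrays of SUM52 with GFP and of untreated SUM52 differed in many lists. Of 14 list medians 13 lay below 0 and 8 under percentile 5 of random lists. Scaled to all probes 3 lay below 0, but relative to all miRNAs 12 to 14 did under each scaling tried. Some of these lists share members, so the counts are not of independent lists. In the miR-17-92 group, an oncogenic cluster and its paralogs, all 11 detected members were lower with GFP, with a median of -2.28 at percentile 0 of random lists that ran from -2.93 to -0.84 over the scalings, and 9 were at or beyond 2-fold lower, such as miR-20b-5p (6.91-fold), miR-20a-5p (5.60-fold) and miR-17-5p (4.84-fold). miR-4267 was 21.3-fold, miR-5096 14.6-fold, let-7g-5p 13.3-fold and miR-31-5p 6.96-fold lower. miR-6789-5p was 8.78-fold, miR-378a-3p 6.84-fold, miR-2861 6.19-fold, miR-374b-5p 4.32-fold and miR-374c-5p 4.18-fold higher, and miR-374a-5p was at 0.37. Of 469 miRNAs 154 were higher and 107 lower at or beyond 2-fold. Basal markers, 7 of 7 below 0, and oncogenic miRNAs, 8 of 11, each had a median of -1.59, at percentiles 0.760 and 0.0700, which ran from -2.33 to -0.25 over the scalings. Both medians are the same value, -1.5853, and may be set by a shared member, so they do not count as separate results. The share of higher ones, 59.0%, ran from 30.1% to 83.4% over the scalings. These arrays differ in GFP and in the experiment they belong to, which cannot be told apart. They also differ in background, with a detection limit of 322 on the untreated array and 103 with GFP. Of the miRNA spots 46.1% and 24.3% were set to 0.01.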

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

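The tests of the miRNAs lower with 4μ8C, of miR-374a-5p and miR-3607-3p and of miRNAs detected on both GFP arrays were chosen only after the results were seen. The control probes named M or MM, which no comparison uses, read 36.6% of their partners with 4μ8C in SUM52 against 3.95% in the control array, and 26.7% against 1.21% in SUM225. miR-8071 had log2 ratios of 2.34 and 1.18 with 4μ8C in SUM52 and SUM225 and of -1.02 and -1.06 with K599A and K907A, a difference of 2.80 (limma adjusted p = 0.157 for the difference, detected on 2 of 7 arrays). miR-297 had 1.93 and 1.59 with 4μ8C and -1.02 and -1.39 with the mutants, a difference of 2.96 (limma adjusted p = 0.142, detected on 2 of 7 arrays). Neither difference passed the threshold. For each miRNA the 2 arrays belong to the inhibitor experiment, so neither was detected with GFP, K599A or K907A. Their mutant ratios are therefore between levels below the detection limit.

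Of the miRNAs at or beyond 2-fold with 4μ8C in both lines, 65 were higher and 22 lower, and of these 6 and 16 were detected on all 4 arrays of the inhibitor experiment. A candidate explanation is a property shared by arrays on which M or MM probes read high: on the MCF10A GFP array, without 4μ8C, the 22 lay below the SUM52 GFP array by a median of -1.22, at percentile 0.810 of matched random sets (2.96 over the 13 detected on both), though cell line differs there too. For the 65 the median was 0.73, at percentile 99.98, which met the prediction written beforehand, but this was ruled undecided after that was seen, since 51 were not detected on both arrays and the other 14 had 0.59, at percentile 94.0. Blocked IRE1 stays open for the 22, whose median on the mutant arrays was -0.23 at percentile 0.645, and is undecided for the 65, whose mutant median was at percentile 74.9 with 18 higher and 21 lower on both mutants. Both medians of the 22 were taken over the same SUM52 GFP array. High readings of these miRNAs on that array would lower both medians, which was not tested. The 22 include miR-320a to miR-320e, whose probes can share signal. Percentiles for the 22 thus count related probes as separate members. Weaker discrimination of near-identical sequences predicted a smaller spread of let-7 members with 4μ8C, and the spread ratios in SUM52 and SUM225 were 1.07 and 1.24, which met the bound written beforehand against it, but 0.921 and 0.964 without normalization, which did not. It had been ruled undecided after the first of these values were seen, because the spread was already 0.899 on the untreated SUM52 array against 2.57 with GFP in the same line, so the untreated array was a poor reference.

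K599A and K907A ratios had a covariance of 0.177, and the highest value simulated for chance error of the shared GFP array was 0.0504. The simulated error was sized on the K599A minus K907A differences, in which the GFP array cancels. The values therefore argue only against a GFP array error as small as that of the mutant arrays. Removing a smooth trend on signal left 99.6% of the covariance. This step could not decide on signal-dependent curvature, since quantile normalization had already given all arrays the same distribution. A larger error of the GFP array, a difference of that array as a whole sample, and an effect of blocked IRE1 all stay open, since there is 1 control array.

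miR-374a-5p and miR-3607-3p were higher on all 4 blocked arrays, and the smaller of their mean log2 ratios on the mutant arrays was 1.63, against a spot spread of 0.0996, where control probes named M or MM read low. This decides nothing about the property of the 4μ8C arrays, since both miRNAs were picked from a fit that includes the mutant arrays and the 1.63 is that of miR-3607-3p, not detected on the SUM52 GFP array. A low reading of miR-374a-5p on the shared GFP array stays open: its GFP over untreated ratio was 0.37, but only spot noise is known for that pair of arrays, which differed at or beyond 2-fold in 55.7% of miRNAs.

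For the common effect, 83 miRNAs had an unadjusted limma p under 0.05. As many came from 5 of the 34 splits of the 7 arrays that could be fitted, the real one included. The others gave 124 or 89, and within their blocks set apart only the arrays with and without 4μ8C, in SUM225 and in SUM52 respectively. Each of these contrasts was counted in both directions. Since they follow the treatment in 1 line, that share does not measure chance, which was not excluded. Of the 12 splits with 1 control in each block only the real one gave as many, and the highest other gave 73. That split also set the 4μ8C arrays of both lines apart from the untreated ones.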

How the results depend on the processing

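Chosen after the data were seen were 3 alternatives: counts over miRNAs detected on both arrays, counts with undetected levels at the lowest detected level of their array, and the common effect over miRNAs detected on all 7 arrays. No paired analysis was possible because each group holds a single array and its number is only an order of listing. Blocks in the common effect are the inhibitor arrays of each line and the mutant and GFP arrays. Signal over background limits the rest, since at most 611 of 2555 miRNAs were detected and undetected levels set most of the higher counts except with K907A and in MCF10A. For all results below, the cause was not tested unless given.

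Totals at or beyond 2-fold, 239 and 233 with 4μ8C in SUM52 and SUM225, 30 and 27 with K599A and K907A, 89 in MCF10A and 261 for GFP over untreated, moved over 1.5 times as follows. Scaling to the 75th percentile of probes detected on all arrays gave 41 for K907A. No normalization gave 288 for K599A, 208 for K907A and 279 for MCF10A. A floor 4 times as high gave 115 for SUM52 with 4μ8C and 17 for each mutant. No filter on detection gave 528, 460, 159, 147, 197 and 678 in the order above, by construction with more miRNAs. A signal of at least 500 gave 63, 130, 13, 13, 51 and 153, with fewer miRNAs. Signals before background subtraction gave 76, 122, 10, 6 and 43 in the first 5 comparisons. Only miRNAs detected on both arrays gave 66, 112, 13, 13, 46 and 105, and undetected levels at the lowest detected level gave 86, 155, 14 and 13 in the first 4 and 162 for GFP over untreated. Without normalization the median of all log2 ratios was 0.51, 1.26, -1.16, -0.94, -1.05 and 0.04 in that order; scaled to all probes it was 1.01 for SUM52 with 4μ8C and 1.55 for GFP over untreated, and scaled to probes detected on all arrays -0.28 for MCF10A and -0.53 for GFP over untreated, against 0.27 for SUM52 with 4μ8C, 0.06 for MCF10A and 0.18 for GFP over untreated as reported.

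The common effect, 0 miRNAs past the threshold, gave 1 with cyclic loess, no normalization, the authors' table, signals before background subtraction, and trend and robust settings of eBayes. It gave 3 scaled to all miRNA probes, 2 with a floor 4 times as high, 2 with a signal of at least 500 and 9 over miRNAs detected on all 7 arrays. Leaving out each array in turn gave 0 to 45, and 45 without the SUM52 GFP array, where by construction the mutants have no control. miR-374a-5p passed in 9 of 23 alternatives (log2 1.81 to 2.60, limma adjusted p 0.00147 to 0.477) and miR-3607-3p in 3 of 22 (0.96 to 1.80, limma adjusted p 0.0289 to 0.477). Of the values for the 10 miRNAs named there, 192 kept their side of the threshold, 20 came past it and 0 reversed. The difference between the inhibitor and the mutants, 0, gave 207 without normalization and 37 without the detection filter. Lists past the threshold with camera, 1, were 0 without normalization and on the 4μ8C arrays alone, 2 with the authors' table, a floor at 8, signals before background subtraction and miRNAs detected on all 7 arrays, 3 with the cell line as block and 4 without the detection filter; leaving out each array gave 1 to 2, with 2 without K599A. let-7 passed in 20 of 23 alternatives and basal markers in 8, while miR-29, fibroblast and muscle markers and miR-17-92 each passed in 1. Correlations stayed from 0.590 to 0.616 between the lines with 4μ8C and from 0.823 to 0.840 between the mutants.

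In single comparisons the sign changed in 442 of 6820 values of named miRNAs and list members and in 105 of 912 list medians. Relative to the median of all ratios under the same setting, which some scalings moved as given above, it changed in 142 and 20 of these, and in 341 and 51 of all the values. It changed for 24 and 6 where the reported value was at or beyond 2-fold, which are given here, but relative to that median for 0 of the 24 and for 1 of the 6, the fibroblast and muscle list; 4776 and 650 of the values moved by less than their spread. For GFP over untreated, scaling to probes detected on all arrays gave miR-4507 -0.0756, miR-652-3p -0.0818, miR-6751-3p -0.11 and miR-192-5p -0.38. Scaling to all probes gave miR-125b-5p 0.27, miR-200c-3p 1.43, let-7b-5p 0.014, miR-106b-5p 0.095, miR-93-5p 0.48, miR-15a-5p 0.31, miR-16-5p 0.70, miR-29a-3p 0.27, miR-29b-3p 0.0049, miR-30b-5p 0.76, miR-30e-5p 0.051 and miR-24-3p 1.02, and with 4μ8C in SUM52 miR-221-3p 0.31 and miR-22-3p 0.20. No normalization gave, with 4μ8C in SUM225, miR-222-3p 0.16, miR-18b-5p 0.022, miR-363-3p 0.29, miR-194-5p 0.31 and miR-22-3p 0.23, and miR-215-5p -0.23 with K599A. Among list medians, scaling to all probes gave, for GFP over untreated, 0.83 for IRE1 cleavage substrates, 0.70 for miR-15/16 and 0.27 for miR-29. No normalization gave, with 4μ8C in SUM225, 0.097 for miR-34 and p53-responsive miRNAs and 0.16 for basal markers. A signal of at least 500 gave -0.83 for fibroblast and muscle markers with 4μ8C in SUM52, with fewer members by construction.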

Other observations

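The comparisons in this part were all chosen after the data were seen. Between cell lines, basal mammary cell markers were higher in MCF10A than in SUM52, both with GFP, with a median log2 difference of 2.93 and 5 of 7 at or beyond 2-fold higher: miR-221-3p was at 2.93, miR-222-3p at 3.29 and miR-125b-5p at 3.88, while miR-205-5p was at -1.83. The epithelial miR-200 and miR-205 list had a median of -2.45 with 4 of 6 at or beyond 2-fold lower, and miR-429, miR-200a-3p and miR-141-3p were not detected in MCF10A. By contrast, miR-200b-3p and miR-200c-3p were detected on both arrays, at -0.55 and -0.77, so the family was not absent from MCF10A. let-7 members had a median of 1.52 with 6 of 9 at or beyond 2-fold higher. The M or MM control probes read 28.4% of their partners on this MCF10A array and 0.546% on the SUM52 array, and the SD of log2 let-7 levels was 0.808 and 2.57. A low reading did not go with a wide spread on all arrays. Untreated SUM225 and SUM52, at 1.21% and 3.95%, had an SD of 0.477 and 0.899. miR-10b-5p was detected in SUM52 and not in MCF10A with GFP or in untreated SUM225. Between untreated SUM225 and SUM52, miR-429 was at 2.26, miR-100-5p at 2.31 and miR-125b-5p at 1.89 higher in SUM225, and miR-106b-5p, miR-93-5p and miR-25-3p, from a single cluster, were at -1.78, -1.61 and -1.71. Each value compares 1 array with 1 array.

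Of 389 miRNAs, 87 were at or beyond 2-fold higher with 4μ8C in SUM225 and 36 lower with IRE1 in MCF10A, and 29 were both, where independent lists would share 8.05. Among the 288 detected on all arrays compared, 4 were both, against 0.826. Overlaps in the same direction, higher in both, were 9 against 5.37 and 4 against 1.42. In SUM52 with 4μ8C the overlap was 17 against 8.94, and 3 against 0.996 among those detected on all arrays, and 7 against 7.29 and 0 against 0.783 were higher in both. With K599A and K907A, 2 and 2 were opposite, against 0.716 and 0.630, and 4 and 3 were higher in both, against 0.752 and 0.762. M or MM control probes went from 1.21% to 26.7% of their partners with 4μ8C in SUM225 and from 28.4% to 21.0% with IRE1 in MCF10A. miR-4267, miR-3613-3p and miR-4668-5p were at or beyond 2-fold higher over GFP with both mutants and also with IRE1 in MCF10A, and lower with GFP than in untreated SUM52 (-4.41, -2.41 and -2.63).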
